A study of Mus musculus with 4 samples.

How the data were processed

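RNA was measured by sequencing in 4 mammary tumours of MMTV-Neu mice on the FVB strain, 2 from AXL knockout animals (AXL KO) and 2 from wild-type animals (WT). MMTV-Neu mice carry the Neu (Erbb2) oncogene under a mammary tumour virus promoter and form mammary tumours. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, purified on columns and made into Illumina libraries. The labels do not say that the replicates came from separate animals, so intervals and p-values measure only the spread between these samples, which may in part be technical.

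The deposited files hold 1 whole-number read count per gene and library, not normalised. The submitters' processing notes list CASAVA 1.8, TopHat2 2.0.10, HTSeq 0.5.3 and DESeq2 1.4.5 with build GRCm38, and give no roles or order. The annotation release, the strand setting and read filters are not given in the sources used here. Because the strand setting is not stated, reads of overlapping genes on opposite strands cannot be told apart. Reads of close paralogs are uncertain as well.

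Each file held 38293 gene rows and 5 summary lines that name no gene. These lines stayed out of library sizes and tests. Of all lines summed, reads outside annotated genes took 5.28% and 6.85% in WT replicates 1 and 2 and 8.11% and 5.90% in AXL KO replicates 1 and 2. Ambiguous reads took 0.981%, 0.635%, 1.85% and 1.09% in the same order. Alignments that were not unique took 23.2%, 28.1%, 25.6% and 24.6%. Of the gene identifiers, 36345 matched a symbol and position in GENCODE release M21, which is on GRCm38, and 1948 did not. Pairs of libraries were compared by a chi-square statistic over genes, which ran from 32.2 to 161 per degree of freedom, so no library repeated another within sampling noise.

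Genes were kept with edgeR's filterByExpr by group, which left 14330 of the 20587 genes with a count. Libraries were scaled with TMM factors. The 2 groups were compared with edgeR 4.0.16 (estimateDisp, glmQLFit with legacy=FALSE, glmQLFTest) without further covariates, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common dispersion was 0.0961, a biological coefficient of variation of 0.31. Levels are given as CPM (gene counts scaled to library size by edgeR) with TMM factors. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and a trend. A list needed at least 3 tested members, which 41 of 44 lists had, and p-values were adjusted over the lists. The same lists were tested with an estimated correlation per list and with fry, which asks whether the genes of a list move on balance 1 way. R was version 4.3.3.

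Named were Axl, then up to 12 genes with the largest rise and 12 with the largest fall in AXL KO past the threshold. They needed a symbol other than Gm with a number or a name ending in Rik, a mean CPM of at least 1, and both AXL KO libraries beyond both WT libraries. Where fewer than 12 passed, the rest were taken by smallest p and are given with values only. Up to 4 members with the smallest p were named in each list described, together with a summary of the AXL family and ERBB family lists. Axl itself filled 1 of the 12 places among the lower genes. The groups, the tests, the gene lists, the naming rule and most alternatives were set before the data were examined. Exceptions are named where they appear. Values of some single genes are not reported here.

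The alternatives were DESeq2 size factors, library totals, no low-count filter, a CPM of at least 1 in 2 libraries, DESeq2 1.42.0, limma-voom, legacy and robust quasi-likelihood settings, an adjusted p of 0.10, a 2-fold minimum, the replicate number as a block, each library left out in turn, camera on ranks, a prior count of 0.5, and lists without shared genes. Alternatives chosen after seeing the data left out the genes of chromosomes 2, 15 and 18, or Axl from the list of its own family.

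The tests were checked on simulated counts for 14330 genes with the means and library sizes of these libraries and 200 changed genes. For AXL KO against WT, edgeR called 3% of genes changed 2-fold, 71.6% of those changed 4-fold and 95.5% of those changed 16-fold, with 15 unchanged genes called. DESeq2 called 13.4%, 83.6% and 95.5%, which is 9, 56 and 63 genes, with 45 unchanged genes called. Some DESeq2 calls in the real libraries may thus be false. No simulated library stood apart from the rest as WT replicate 2 did, so these percentages need not hold for the real libraries. When the 20 endothelial markers were shifted 1.6-fold, camera gave an adjusted p of 2.53e-05 with the preset correlation and 0.999 with an estimated one, and called 0 other lists with the preset correlation. With an estimated correlation the known shift was thus not called. The simulated genes varied independently of each other, while the interferon list had an estimated correlation of 0.97 in the real libraries. The simulation therefore does not show how often the preset correlation calls lists of correlated genes wrongly.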

Results

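The series compared gene expression in mammary tumours of MMTV-Neu mice that lacked AXL with tumours of mice that carried the gene, with 2 tumour libraries in each group. AXL is a receptor tyrosine kinase of the TAM family and binds the ligand GAS6. Reads counted in genes came to 21276336 and 18929743 in WT replicates 1 and 2, and to 19161051 and 33131739 in AXL KO replicates 1 and 2. Between 18015 and 18879 genes had a count in a library. The descriptions of 3 libraries share a prefix, and that of AXL KO replicate 2 has another. The second prefix holds 1 library of 1 group, so no comparison can be made within it, and the values without AXL KO replicate 2 are those within the first prefix.

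Axl transcripts were 10.05-fold lower in the AXL KO tumours. Axl (ENSMUSG00000002602) lies on the minus strand of chromosome 7 from 25757273 to 25788705 in GRCm38. WT replicates 1 and 2 had 1321 and 673 Axl counts, and AXL KO replicates 1 and 2 had 89 and 163. The level was 48.5 ± 18.8 CPM in WT and 4.82 ± 0.0954 CPM in AXL KO (SD, n = 2 each), which put the knockout libraries at 9.80% and 10.1% of the WT mean. Reads on Axl remained in both knockout libraries, and counts per gene do not show which part of the transcript they cover. The log2 difference was −3.33 with a standard error of 0.35. By edgeR's quasi-likelihood test its unadjusted p was 0.000184 and its adjusted p over all 14330 genes 0.9997, so the difference did not pass that test. Axl passed in DESeq2, with a log2 difference of −3.34 and an adjusted p of 4.17e-13. It passed in edgeR when WT replicate 1 was left out, with an adjusted p of 0.0237. Leaving out WT replicate 2, AXL KO replicate 1 or AXL KO replicate 2 gave edgeR adjusted p-values of 0.155, 0.9998 and 0.9997. Within the first prefix the log2 difference was −3.37.

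Beside Axl, Hmox1, the metallothionein genes Mt1 and Mt2 and 8 further genes were named at lower levels in AXL KO tumours, though none passed edgeR's test. Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, was at 280 ± 8.74 CPM in WT and 108 ± 20.9 CPM in AXL KO (SD, n = 2 each), with a log2 difference of −1.37 ± 0.21 (SE). The metallothionein genes Mt2 and Mt1, which encode metal-binding proteins, were 3.83-fold and 1.99-fold lower. Lmx1b, a LIM homeodomain transcription factor gene, was 2.60-fold lower, Ramp1, which encodes a receptor activity modifying protein, 2.89-fold lower, and Cyp2f2, a cytochrome P450 gene, 6.94-fold lower. Bcl3, which encodes an atypical IκB protein, was at 11.04 and 13.3 CPM in the WT libraries and at 4.38 and 5.22 CPM in the AXL KO libraries. Without WT replicate 2 the log2 difference of Mt2 moved from −1.94 to −1.29. Shisa8, Plekhh2, Irf2bp2 and Gse1 completed the lower genes, by 2.36-fold, 3.34-fold, 1.76-fold and 1.56-fold.

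Among the genes at higher levels in AXL KO tumours, Nfasc, which encodes the cell adhesion protein neurofascin, was at 2.09 ± 1.48 CPM in WT and 17.6 ± 6.19 CPM in AXL KO (SD, n = 2 each). Ltf, which encodes the milk and neutrophil protein lactoferrin, was 3.24-fold higher, Adh1, an alcohol dehydrogenase gene, 4.79-fold higher, and the protocadherin gene Pcdhb12 5.57-fold higher. Mat1a, whose product makes S-adenosylmethionine, was at 0.0935 and 0.524 CPM in the WT libraries and at 4.38 and 3.57 CPM in the AXL KO libraries. Ucp1, the uncoupling protein gene of brown fat, was at 0.0935 and 0 CPM in WT and at 5.88 and 0.96 CPM in AXL KO. The histamine receptor gene Hrh3 and the zinc finger gene Zfp605 were 5.83-fold and 3.04-fold higher. Ccdc158, Zbtb20, Chsy1 and the membrane-type metalloproteinase gene Mmp16 were 2.74-fold, 2.01-fold, 1.81-fold and 1.6-fold higher. Pcdhb12, Mt1, Mt2 and Zfp605 belong to families with close copies, so their counts are uncertain.

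**Figure D1:**
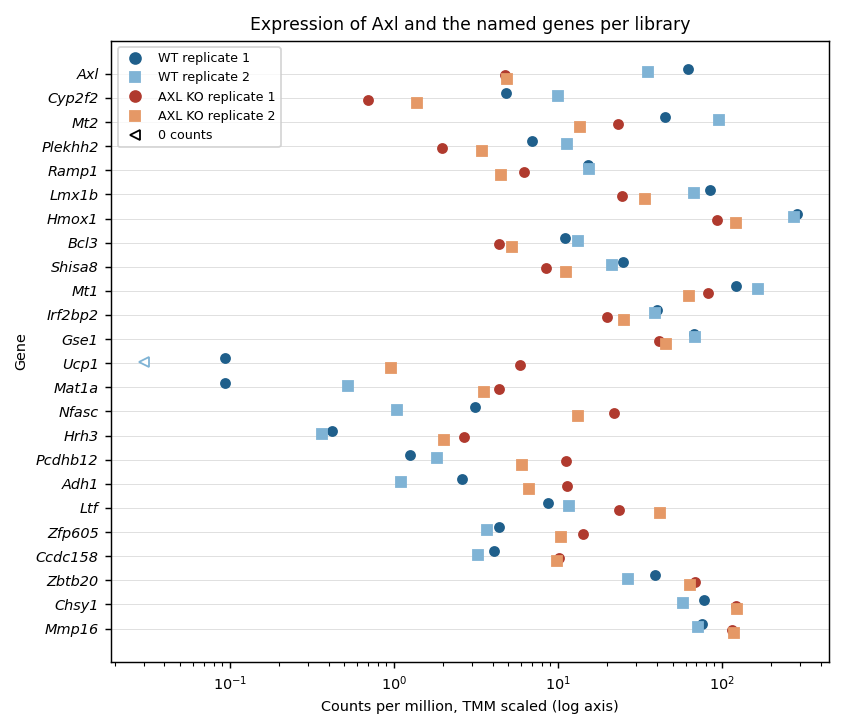
CPM with TMM scaling on a log axis, for Axl and the 23 other named genes on the vertical axis, with 1 point per library and an open triangle for a library with 0 counts. Both AXL KO libraries lie below both WT libraries from Axl down to Gse1 and above them from Ucp1 down to Mmp16. The naming rule required this of the genes other than Axl, so it is not a result.

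No gene passed edgeR's quasi-likelihood test at an adjusted p of 0.05, a count of 0 of 14330. At an unadjusted p under 0.05 there were 314 genes, 165 higher and 149 lower in AXL KO, where 5% of the genes tested would be 716. The named genes above, other than Axl, were therefore taken by smallest p, from 0.0011 for Hmox1 to 0.0124 for Gse1, and none of them passed. Limma-voom called 0 genes, with 285 at an unadjusted p under 0.05, and DESeq2 called 17. Leaving out WT replicate 1 gave 216 edgeR calls, 134 higher and 82 lower, while leaving out WT replicate 2, AXL KO replicate 1 or AXL KO replicate 2 gave 0, with 394, 113 and 220 genes at an unadjusted p under 0.05. Both AXL KO libraries lay beyond both WT libraries for 4185 genes, 29.2% of those tested, where chance gives 33.3%.

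DESeq2 called 17 genes, 10 higher and 7 lower in AXL KO. The lower genes were Axl, Hmox1 (adjusted p = 0.00224), C130021I20Rik (0.00496), Cyp2f2 (0.0153), Lmx1b (0.0208), Ramp1 (0.0234) and Mt2 (0.0436). Of the higher genes, Nfasc (0.00224), Pcdhb12 (0.0114), Mat1a (0.0172), Ucp1 (0.0414), Ltf (0.0481) and Zfp605 (0.0496) are described above. The other 4 were 1700012B07Rik (0.00491), Gm11683 (0.00491), 4930525G20Rik (0.0344) and Smoc1 (0.0344), and with C130021I20Rik they were chosen after their values were seen. Smoc1, which encodes a secreted calcium-binding matrix protein, was at 19.9 and 4.14 CPM in the WT libraries and at 68.5 and 94.3 CPM in the AXL KO libraries. Gm11683 lies within 1700012B07Rik on the opposite strand of chromosome 11, so their reads cannot be told apart without the strand setting. C130021I20Rik lies next to Lmx1b on chromosome 2. Without WT replicate 1, WT replicate 2, AXL KO replicate 1 or AXL KO replicate 2 DESeq2 called 1088, 29, 23 and 9 genes, of which 17, 10, 3 and 3 were among the 17.

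Type I interferon response genes were higher in AXL KO tumours, as a list, than other genes by camera with the preset correlation (adjusted p = 1.17e-17), and not with an estimated one (adjusted p = 0.917 with an estimated correlation). The test with an estimated correlation also missed the known shift in the simulated counts. A call lost under it, here or below, therefore cannot decide whether a list changed. All 30 tested members had a positive log2 difference, with a list median of 1.42. In both AXL KO libraries 27 were higher than in both WT libraries, as were 2111 of all 14330 genes tested. The members moved together (estimated correlation 0.97), so 27 of 30 is not a count of independent genes. Examples are the antiviral effector genes Mx1, Mx2 and Oas2 and the chemokine gene Cxcl9, best known as a target of interferon gamma. Mx1 was at 9.17 and 1.31 CPM in WT and at 16.8 and 25.9 CPM in AXL KO, and Oas2 at 23.4 and 3.51 CPM in WT and at 33.3 and 61.2 CPM in AXL KO. Mx2 was at 16.4, 1.73, 32.6 and 33.2 CPM and Cxcl9 at 3.13, 0.89, 3.47 and 8.43 CPM in WT replicates 1 and 2 and AXL KO replicates 1 and 2. Of its members 0 passed edgeR over all genes, 0 adjusted over the list alone and 0 had an unadjusted p under 0.05. WT replicate 2 stood far below the other libraries for these genes, with a mean deviation of −2.78 on the log2 scale against 0.55, 0.96 and 1.27 in WT replicate 1, AXL KO replicate 1 and AXL KO replicate 2. Without WT replicate 2 the median was 0.62, and without WT replicate 1 it was 3.8. Camera with the preset correlation takes the genes of a list as nearly independent. Its p-values for this list therefore do not measure the spread between tumours. With WT replicate 2 left out Mx1, Mx2, Oas2 and Cxcl9 had log2 differences of 1.22, 1.01, 1.02 and 0.95, and with WT replicate 1 left out 4.03, 4.25, 3.75 and 2.75.

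Antigen presentation genes and NK, T cell and macrophage markers were also higher as lists with the preset correlation, and each of these 5 lists lost its call with an estimated one (adjusted p = 0.917 with an estimated correlation for each). B and plasma cell markers were not called (median 0.07, camera adjusted p = 0.707). For MHC class I antigen presentation all 16 tested members had a positive log2 difference (median 0.79, camera adjusted p = 7.5e-07), with Erap1 at 133 and 46.2 CPM in WT and at 136 and 162 CPM in AXL KO. The proteasome activator genes Psme1 and Psme2 and the MHC class I transactivator gene Nlrc5 had log2 differences of 0.43, 0.42 and 1.45. All 9 tested NK and cytotoxic markers had positive differences (median 0.79, adjusted p = 0.000789), among them Klrk1 at 1.6, Klrd1 at 1.35, Ncr1 at 1.24 and the granzyme gene Gzmc at 2.07. The 9 tested MHC class II genes did too (median 0.67, adjusted p = 0.0023), led by H2-Aa at 0.93, Cd74 at 0.89, H2-Ab1 at 0.88 and H2-DMa at 0.71. Of 11 T cell markers 8 were positive (median 0.65, adjusted p = 0.0371), including Cd2 at 1.01, Cd3d at 0.70 and Zap70 at 0.65, and of 22 macrophage markers 18 were positive (median 0.20, adjusted p = 0.0304), with Lyz2 at 0.34, Arg1 at 0.36, Fcer1g at 0.43 and Cd14 at −0.57. Both AXL KO libraries lay above both WT libraries for 7 of the 16 MHC class I genes, 3 of 9 NK and cytotoxic markers, 1 of 9 MHC class II genes, 0 of 11 T cell markers and 3 of 22 macrophage markers, and below both for 1 macrophage marker. Of the members of these 5 lists 0 passed edgeR over all genes or adjusted over the list alone. An unadjusted p under 0.05 was reached by 1 member each of the NK and MHC class II lists and 0 of the other 3. H2 genes have close copies, so their counts are uncertain.

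WT replicate 2 was the lowest library for each of these 5 lists, with mean log2 deviations of −2.08 for MHC class I, −1.61 for NK and cytotoxic markers, −0.72 for MHC class II, −1.51 for T cell markers and −0.38 for macrophage markers. Without it the medians were 0.06, 0.26, 0.27, −0.15 and −0.03, with camera adjusted p-values of 0.59, 0.625, 0.484, 0.0718 and 0.484, so the T cell and macrophage medians turned negative and none of the 5 lists was called. Without AXL KO replicate 2, MHC class II, T cell and macrophage lists were not called either (medians 0.11, 0.18 and 0.03, adjusted p = 0.431, 0.357 and 0.662). The T cell call was also lost with the stricter low-count filter (median 0.29, adjusted p = 0.0967) and without the genes of chromosomes 2, 15 and 18 (0.45, 0.0687). Without WT replicate 1 the 5 medians were 3.38, 2.61, 1.15, 2.33 and 0.60. The single genes moved as well. Between the fits without WT replicate 2 and without WT replicate 1, the log2 difference went from 0.03 to 0.98 for Psme1, 0.13 to 0.80 for Psme2, 0.16 to 1.68 for Erap1, 0.52 to 5.02 for Nlrc5, 0.78 to 3.89 for Klrk1, 0.74 to 2.5 for Klrd1, 0.50 to 3.04 for Ncr1, 0.51 to 1.91 for Cd2, −0.07 to 2.33 for Zap70, −0.14 to 3.47 for Cd3d, 0.09 to 0.89 for Fcer1g and −0.27 to −0.82 for Cd14. Without AXL KO replicate 2, H2-Aa was at 0.33, Cd74 at 0.11, H2-Ab1 at −0.0049, H2-DMa at 0.04 and Lyz2 at 0.14, and without AXL KO replicate 1 Arg1 was at 0.06.

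Lipid synthesis and milk genes were the remaining lists that were higher with the preset correlation, and both lost the call with an estimated one (adjusted p = 0.917 with an estimated correlation for each). Of 24 fatty acid and cholesterol synthesis genes 18 had positive differences (median 0.14, camera adjusted p = 0.00448), with Thrsp at 34.7 ± 6.0 CPM in WT and 72.7 ± 21.7 CPM in AXL KO (SD, n = 2 each) and Insig1, Cyp51 and Idi1 at log2 differences of 1.13, 0.55 and 0.42. Of 14 milk genes 11 had positive differences (median 0.24, adjusted p = 0.0133), with the lactoferrin gene Ltf at 1.69, the milk fat globule enzyme gene Xdh at 0.60, the transferrin gene Trf at 1.27 and the casein gene Csn1s1 at 2.30. Csn1s1 was at 1.496 and 45.4 CPM in WT and at 190 and 41.0 CPM in AXL KO, so its groups overlapped. Both AXL KO libraries lay above both WT libraries for 7 lipid synthesis and 5 milk genes. In both lists 0 members passed edgeR over all genes or adjusted over the list alone, with 2 members of each at an unadjusted p under 0.05. WT replicate 2 was the lowest library for lipid synthesis (mean log2 deviation −0.33), and WT replicate 1 the lowest for milk genes (−1.15). The lipid call was lost without WT replicate 2 or AXL KO replicate 2 (adjusted p = 0.184 and 0.221), and the milk call without WT replicate 1 or AXL KO replicate 1 (0.333 and 0.226) or with camera on ranks (0.0731). With 1 library left out the medians ran from 0.04 to 0.34 for lipid synthesis and from 0.24 to 0.69 for milk genes. The log2 differences then ran from 0.63 to 1.88 for Insig1, 0.31 to 0.74 for Cyp51, 0.25 to 0.56 for Idi1, 0.60 to 1.7 for Trf and 0.81 to 6.26 for Csn1s1. Adipocyte markers were also lowest in WT replicate 1, with a mean log2 deviation of −0.72 against 0.30, 0.13 and 0.29 in WT replicate 2 and AXL KO replicates 1 and 2.

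Mitosis genes and hypoxia targets were lower in AXL KO tumours as lists with the preset correlation, and both lost the call with an estimated one (adjusted p = 0.917 with an estimated correlation for each). All 24 mitosis genes had negative log2 differences (median −0.84, camera adjusted p = 1.57e-11), with the mitotic kinase gene Plk1 at −1.0, Ube2c at −1.19, Cdc20 at −0.84 and the cyclin gene Ccnb2 at −0.84. Of 29 hypoxia and HIF targets 2 had a positive difference (median −0.78, adjusted p = 3.23e-07). Ndrg1 was at 12.1 and 275 CPM in WT and at 8.44 and 9.96 CPM in AXL KO, and Egln1, Pfkfb3 and Adm had log2 differences of −0.80, −1.6 and −2.44. In WT replicates 1 and 2 and AXL KO replicates 1 and 2, Egln1 was at 63.2, 105, 49.4 and 47.0 CPM, Pfkfb3 at 21.04, 67.9, 12.6 and 16.7 CPM and Adm at 3.13, 22.8, 2.62 and 2.16 CPM, so WT replicate 2 was the highest library for each of these 4 genes. Without WT replicate 2 the log2 differences of Ndrg1, Egln1, Pfkfb3 and Adm were −0.39, −0.39, −0.52 and −0.40, and those of Plk1, Ube2c, Cdc20 and Ccnb2 −0.47, −0.39, −0.34 and −0.32. Both AXL KO libraries lay below both WT libraries for 8 of the 24 mitosis genes and 6 of the 29 hypoxia targets. In both lists 0 members passed edgeR over all genes or adjusted over the list alone, with 0 mitosis genes and 4 hypoxia targets at an unadjusted p under 0.05. WT replicate 2 was the highest library for both, with mean log2 deviations of 0.99 for mitosis genes and 1.22 for hypoxia targets, while the other libraries lay between −0.63 and −0.14 and between −0.48 and −0.31. Without WT replicate 2 the mitosis median was −0.14 (adjusted p = 0.0572) and the hypoxia median turned to 0.03 (adjusted p = 0.901). Without WT replicate 1 they were −1.23 and −1.30.

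TGF-beta genes, EMT genes and the TAM receptors and ligands were the other lists that were lower with the preset correlation, and the 3 lost the call with an estimated one (adjusted p = 0.917 with an estimated correlation for each). In the TAM list (5 members, median −0.53, camera adjusted p = 0.00159) Axl is itself the knocked-out gene, so the call of that list is partly set by the design. Without Axl, an alternative chosen after seeing the data, the 4 other members were not called (median −0.39, adjusted p = 0.0898), though they were called when AXL KO replicate 2 was also left out (median −0.55, adjusted p = 0.0204). Gas6, Pros1 and Tyro3 had log2 differences of −0.54, −0.53 and −0.24, and Mertk had 0.16. Its 1 member past edgeR's test adjusted over the list alone was Axl (adjusted p = 0.00092), and 0 passed over all genes. Of 23 TGF-beta ligands, receptors and targets 5 were positive (median −0.31, adjusted p = 0.0128), with Ccn1 at −0.89, Smad6 at −0.85, Bambi at −1.44 and Smad2 at −0.54. Of 16 EMT and mesenchymal genes 2 were positive (median −0.25, adjusted p = 0.0371), with Cdh2 at −0.97, Loxl2 at −0.84, Twist1 at −0.71 and Snai1 at −0.89, and all 16 overlapped between the groups. The EMT call was lost with library totals (median −0.26, camera adjusted p = 0.0572) and with the stricter low-count filter (−0.24, 0.0512). It was also lost without the genes of chromosomes 2, 15 and 18 (−0.4, 0.0779). Both AXL KO libraries lay below both WT libraries for 5 TGF-beta genes. In the TGF-beta and EMT lists 0 members passed edgeR over all genes or adjusted over the list alone, with 1 and 0 at an unadjusted p under 0.05.

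WT replicate 2 was the highest library for TGF-beta and EMT genes, with mean log2 deviations of 0.29 and 0.59. Stromal markers moved with the EMT genes over the libraries. The mean log2 deviations in WT replicates 1 and 2 and AXL KO replicates 1 and 2 were −0.20, 0.59, −0.71 and 0.33 for EMT genes, −0.16, 0.41, −0.72 and 0.47 for collagens and matrix proteins, and −0.16, 0.33, −0.54 and 0.37 for fibroblast markers. The last 2 lists were not called with all libraries (camera adjusted p = 0.0782 and 0.353). Their median log2 differences were 0.19 and 0.23 without AXL KO replicate 1, and −0.96 and −0.63 without AXL KO replicate 2. Camera with the preset correlation called both lists in each of these fits, in opposite directions. A call by that test can thus rest on 1 library. The EMT median turned to 0.08 without WT replicate 2 (adjusted p = 0.916) and also without AXL KO replicate 1 (0.08, adjusted p = 0.266). The TGF-beta list was not called without WT replicate 1 or AXL KO replicate 1 (adjusted p = 0.198 and 0.147), nor the TAM list without WT replicate 1 (0.0956). With 1 library left out the medians ran from −0.33 to −0.11 for TGF-beta genes, from −0.81 to −0.23 for the TAM list and from −1.0 to 0.08 for EMT genes. For the single genes the log2 differences then ran from −0.95 to −0.23 for Gas6, −0.85 to −0.11 for Pros1, −1.32 to −0.57 for Ccn1, −1.2 to −0.39 for Smad6, −2.16 to 0.05 for Bambi, −0.79 to −0.23 for Smad2, −1.65 to 0.24 for Cdh2, −2.03 to −0.19 for Loxl2, −1.14 to −0.10 for Twist1 and −1.56 to 0.41 for Snai1.

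**Figure D2:**
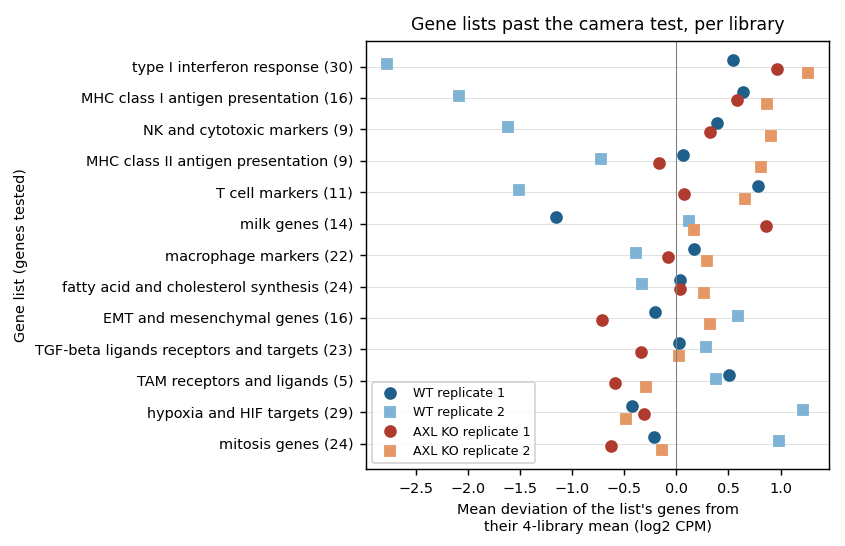
Mean deviation of the genes of each of the 13 lists past camera from their mean over the 4 libraries, in log2 CPM on the horizontal axis, with 1 point per library and the number of genes tested in brackets on the vertical axis. WT replicate 2 lies at −2.78 for the interferon list and at 1.22 for the hypoxia list, apart from the other 3 libraries.

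In all, 13 of 41 lists passed camera with the preset correlation, 8 higher and 5 lower (4 lower with Axl left out of the TAM list), and 0 passed with an estimated correlation or with fry (adjusted p = 0.94 for each list). Without WT replicate 2 camera called 8 lists, of which 4 were among the 13, in the same direction: interferon, milk, TAM and TGF-beta genes. The TAM list without Axl was not called there (adjusted p = 0.184). The other 4 were higher, namely adipocyte markers (median 0.72, adjusted p = 6.02e-08), ribosomal protein genes (0.15, 0.00118), mitochondrially encoded genes (0.37, 0.00918) and nuclear oxidative phosphorylation genes (0.10, 0.0104). With an estimated correlation none of these 8 lists was called there. That test missed the known shift in the simulated counts too, so its missing calls cannot decide whether the lists changed. Of the 17 DESeq2 calls, Axl and Ltf were members of the 13 lists. With all libraries, the 28 lists not called had camera adjusted p-values from 0.0691 for DNA replication genes to 0.9975 for luminal mammary genes. Among cell type lists, endothelial markers had a median log2 difference of 0.06 (adjusted p = 0.837), fibroblast markers −0.12 (0.353), dendritic cell markers 0.25 (0.0782) and adipocyte markers 0.08 (0.189). Of 15 ERBB receptors and ligands 5 were higher and 5 lower in both AXL KO libraries (median −0.28, adjusted p = 0.408). They include the ligand genes Nrg2, Hbegf, Nrg1 and Epgn at log2 differences of −0.67, −2.01, −1.16 and −1.34, and the receptor gene Egfr at 0.40. Erbb2, where reads of the transgene can count, was at 10970 and 12590 CPM in WT and at 19780 and 19980 CPM in AXL KO. It passed neither edgeR (adjusted p = 0.9997) nor DESeq2 (adjusted p = 0.462). Of the 15 ERBB receptors and ligands 0 had an unadjusted p under 0.05 in edgeR. The median, mean and test differed in sign for the luminal, peripheral nerve, oxidative phosphorylation and mast cell lists. Neutrophil markers, replication-dependent histone genes and sex-linked genes had fewer than 3 tested members each.

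WT replicate 2 stood apart from the other 3 libraries across the transcriptome. The first principal component held 64.1% of the variance and placed it at 75.2, against −23.1, −27.2 and −24.9 for WT replicate 1 and AXL KO replicates 1 and 2. It differed by over 2-fold from the mean of the other 3 libraries for 1997 genes, where the other libraries did so for 634 to 1052 genes. Genes of chromosomes 2, 15 and 18 were higher in it as a whole, by 1.4-fold, 1.42-fold and 1.85-fold against the other autosomes, over 877, 435 and 281 genes with a mean CPM of at least 5. With the genes of these chromosomes left out, an alternative chosen after seeing the data, edgeR again called 0 genes, with 283 at an unadjusted p under 0.05, and camera called 14 lists, 11 of them among the 13.

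**Figure D3:**
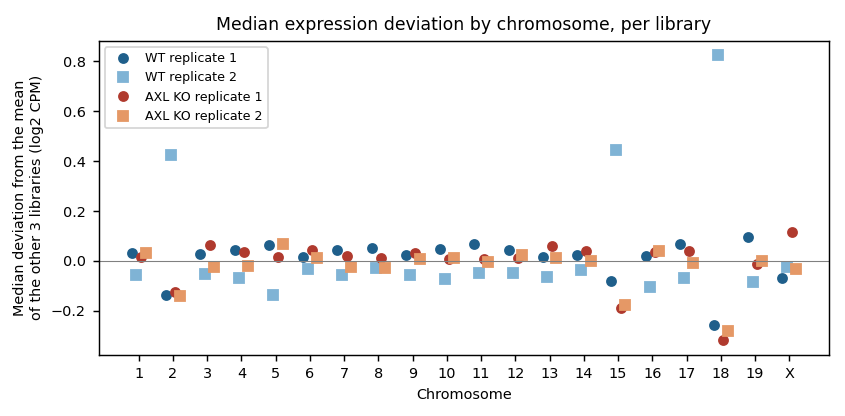
Median deviation of the genes on each chromosome (horizontal axis) from the mean of the other 3 libraries, in log2 CPM on the vertical axis, with 1 point per library. WT replicate 2 lies at 0.42 on chromosome 2, 0.45 on chromosome 15 and 0.83 on chromosome 18.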

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

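With 1 library left out, 33 of the list values kept direction and side of the threshold, 14 kept direction only and 5 reversed. Of the named gene values 279 kept both, 7 came to pass and 6 reversed. None of these genes passed edgeR with all libraries, so a kept value only has the same sign and no call. Its size may have moved, as for Ndrg1, from −3.96 with all libraries to −0.39 without WT replicate 2. Under the other settings 123 list values kept both and 33 kept direction only, and 699 named gene values kept both while 11 came to pass, all 11 in DESeq2. DESeq2 gave Axl a log2 difference of −3.34 and called 17 genes, and the number of lists called was 0 with an estimated correlation and 0 with fry. Leaving out 1 library moved Axl between −3.68 and −2.87, the edgeR count between 0 and 216 genes and the list count between 8 and 17. Without WT replicate 2 these reversed: Bambi (0.0534, from −2.16), Cdh2 (0.24, from −1.65), Snai1 (0.41, from −1.56), Zap70 (−0.0735, up to 2.33) and Cd3d (−0.14, up to 3.47), and the medians of hypoxia (0.033, from −1.30), macrophage (−0.034, up to 0.60), EMT (0.082, from −1.0) and T cell lists (−0.15, up to 2.33). H2-Ab1 reversed without AXL KO replicate 2 (−0.0049, up to 1.41), and the EMT median without AXL KO replicate 1 (0.077). The cause was not tested. With 1 library left in a group, that library is assumed to vary like the other group. Depth limits genes such as Ucp1 and Mat1a, with few or 0 counts in a WT library. The alternatives without chromosomes 2, 15 and 18 and without Axl in the TAM list (12 lists called) were chosen after seeing the data.

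The labels do not say whether libraries with the same replicate number share anything else. Deviations of same-numbered libraries correlated at −0.045 across genes. With 2 libraries per group this cannot show whether they are paired. With the replicate number as a replicate block, edgeR called 0 genes, with 571 at an unadjusted p under 0.05 and an adjusted p of 0.108 for Axl, and camera called 16 lists, the 13 included. The block moved by over 1.5 times the medians of the list type I interferon response (2.16), the list MHC class I antigen presentation (1.69), the list NK and cytotoxic markers (1.42), the list milk genes (0.56) and the list EMT and mesenchymal genes (−0.44).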

Other observations

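The tests of leukocyte share, of library scaling, of a few strongly changed genes, of whole chromosomes and of flanking DNA were chosen after the result was seen. After Ucp1 was seen, 8 other genes known from brown fat or from adipocytes in general were looked up. None of the 8 passed edgeR (adjusted p = 0.9997 for each) or DESeq2 (adjusted p from 0.192 for Prdm16 to 1). Prdm16, a transcription factor gene of brown fat, was at 1.22 and 0.262 CPM in WT and at 5.07 and 5.07 CPM in AXL KO, and Fabp3 at 0.0468 and 0 CPM in WT and at 1.55 and 0.57 CPM in AXL KO. Cidea was at 0.281, 1.36, 2.83 and 2.07 CPM in WT replicates 1 and 2 and AXL KO replicates 1 and 2, and Cox7a1 at 10.9, 3.82, 17.8 and 13.7 CPM. Cox8b (3.55, 0.524, 7.48 and 3.54 CPM) and Dio2 (0.561, 1.47, 0.908 and 2.52 CPM) overlapped between the groups. The general adipocyte genes Adipoq and Plin1 were at 5.19, 14.1, 12.9 and 13.3 CPM and at 2.20, 4.87, 3.10 and 5.10 CPM in the same order, so their groups overlapped. No test of this set as a list was made, since it was picked from the data.

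In WT replicate 2 some single genes were looked up after its values were seen, beside the listed genes B2m and Nlrc5. B2m was at 395 CPM there against 4720, 5844 and 5037 CPM in WT replicate 1 and AXL KO replicates 1 and 2, and Nlrc5 at 3.87 CPM against 88.0, 102 and 149 CPM. The receptor gene Ifnar1 (55.9 CPM against 61.0, 58.7 and 66.5) and the kinase gene Jak1 (305 CPM against 339, 366 and 429) lay closer to the other libraries. The same library had Vegfa at 267 CPM against 45.6, 86.0 and 41.1 CPM, and Pgf at 106 CPM against 21.7, 11.5 and 12.7 CPM.

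For the low interferon and MHC class I transcripts of WT replicate 2, a smaller share of leukocytes was weighed first. If leukocytes carried these transcripts, a smaller share would lower macrophage markers as much. The interferon median lay 2.975 log2 units below the macrophage median (a difference of −2.975, with an interquartile range of 0.52 for the macrophage markers). For transcripts carried by leukocytes, this argues against a lower share of all leukocytes as the whole cause. Counts of bulk tissue do not show which cells carried them. T cell and NK markers had median deviations of −2.07 and −2.0 in that library against −3.6 for the interferon list, with interquartile ranges of 1.36 and 1.22, so a lower share of T and NK cells alone stays open. Library scaling is argued against too, since a factor moves all genes alike, while the interferon median deviation minus that of all tested genes was −3.604, with an interquartile range of 0.69 over all tested genes. No explanation within the tumour cells was tested, and with 1 such library the design cannot tie the pattern to the presence of AXL.

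For the higher expression along chromosomes 2, 15 and 18 in WT replicate 2, GC content was argued against, since after removal of the GC trend the smallest median excess was 0.495. A few strongly changed genes were argued against as well, since at least 85.7% of the genes of each chromosome lay above the median of the other autosomes. Extra copies of whole chromosomes in that tumour are a candidate explanation, since 100% of the 10 Mb windows with 5 or more genes lay above that median. DNA copy number was not measured here, so this remains a hypothesis.

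For the 314 genes at an unadjusted p under 0.05, DNA that flanks the targeted allele was weighed. Within 10 Mb of Axl 1.805% of genes (5 of 277, exact 95% interval 0.589% to 4.16%) had such a p, against 2.19% of the 14052 other genes, which argues against it for the genome as a whole. It stays open for single genes near Axl, such as Cyp2f2, Bcl3 and Plekhg2. The AXL KO against WT split gave the fewest such genes of the 3 splits of the 4 libraries into 2 and 2. It gave 314, where 5% of the genes tested would be 716. Replicates 1 against replicates 2 gave 492. WT replicate 1 and AXL KO replicate 2 against the other 2 libraries gave 867. In each split 0 genes passed the adjusted threshold. The 3 splits are too few to give a share under 0.05.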
